A study of Caenorhabditis elegans with 6 samples.

How the data were processed

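RNA from embryos of the nematode Caenorhabditis elegans was sequenced in 6 samples, 3 from dot-1.1; ced-3 double mutants and 3 from ced-3 single mutants, which served as controls. Per the labels' protocols, animals were grown at 20 °C on E. coli OP50, egg-laying adults were dissolved in alkaline hypochlorite to release their eggs, total RNA was extracted with a miRNeasy kit, ribosomal RNA was depleted, and strand-specific libraries with fragments of about 250 to 300 bp were prepared with a NEBNext kit whose second strand is digested before amplification. The labels call the samples biological replicates and number them 1 to 3 in each genotype. Their descriptions give the libraries of both genotypes the same non-consecutive numbers in this order. They do not say whether a number marks a shared day or culture.

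The values are raw read counts per gene as deposited by the authors, whole numbers in 1 table with a column for each library. Each column was assigned to its sample through the sample's own description in the labels. Reads were aligned with HISAT2 2.0.5, StringTie was used, and the genome build was WBcel235, per the submitters' processing notes. The counting program, the annotation release, the read filters, the treatment of reads that map to several places and whether counting used the strand are not given in the sources used here. Counts of near-identical paralogues and of overlapping or antisense genes are therefore uncertain. Overlaps of exons on the same strand are named beside the genes they concern. On the other strand, besides the overlaps named there, hpo-26 overlaps acs-1, nos-2 overlaps him-14, hsp-17 overlaps F52E1.14, srt-42 overlaps Y46H3A.4, alh-8 overlaps F13D12.8, B0457.10 overlaps B0457.15, unc-22 overlaps ZK617.19 and ZK829.9, zfp-1 overlaps F54F2.7 as well as ztf-1, and cpr-4, F42A9.6 and iff-1 each overlap a non-coding or unnamed gene.

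The table holds 46659 rows named by C. elegans sequence names, of which 11671 were at 0 in every library. Names, biotypes and coordinates came from the Ensembl release 115 annotation of WBcel235, matched by exact sequence name. Matching gave 46180 rows 1 gene each, left 476 without a match, 70 of them assembled loci named XLOC, and left 3 with more than 1 gene. Unmatched and ambiguous rows held 0.521% of all counts and stayed in the library totals and tests under the names of the table. Mitochondrial protein-coding genes are named by their RefSeq symbols through overlapping coordinates, and the list of mitochondrial genes, which had been fixed under other symbols, was taken as the protein-coding genes of the mitochondrial chromosome.

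Library totals ran from 66316445 to 77957224 counts. A count of 0 allows up to 3 counts, or 0.0385 to 0.0452 CPM (counts scaled by the library total) depending on the library. This floor covers counting error only, since reads amplified by PCR are not independent molecules. To look for a library deposited more than once, the counts of the replicates of each genotype were compared: the chi-square statistic per degree of freedom was 115 to 224 in these comparisons, so none of them agrees within sampling noise. This does not show that the samples came from separate cultures. That they are biological replicates is taken from the labels.

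Genes were tested with edgeR 4.0.16 in R 4.3.3: genes with too few counts were removed by filterByExpr, which left 17365, libraries were scaled by TMM, and the double mutants were compared with the single mutants by the robust quasi-likelihood test with genotype as the only term. P-values are two-sided and adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. CPM values include the TMM factors, except for the mitochondrial genes and the floors, which use the library totals. Fold changes are double mutant over single mutant. The spread between replicates corresponded to a biological coefficient of variation of 0.265.

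The main fit was planned without a block, since the labels name no shared day or batch. Whether the replicate numbers pair the samples was then decided from the data. Over the tested genes, the deviations from the genotype mean correlated at 0.17 to 0.32 between libraries of the same number and at -0.24 to 0.059 between other libraries of different genotypes, and all 6 libraries correlated best with the library of their own number. All 3 pairs were above 0.1, the limit used for pairing, so the numbers were taken to pair the samples. The decision rests on these correlations, which are limited evidence. Deviations from a genotype mean cancel out over its libraries, so positive correlations within numbers push the other correlations down. With 3 libraries per genotype, a best match by number can also arise by chance. The labels number both genotypes alike but do not say that a number marks a pair. A second fit therefore had the replicate number as a block, which lowered the coefficient of variation to 0.201, and its values are given beside those without the block where they differ in the call.

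Both fits were tested on simulated counts drawn with the real means and library sizes and the dispersions of each fit. In each of 5 draws 200 genes were changed, over an average of 16769 genes without the block and 16699 with it. Without the block, 41.4% of the genes changed 2-fold and 78.6% of those changed 4-fold were called in the right direction, and 8.21% of the calls were unchanged genes. With the block these values were 58.8%, 84.2% and 13.6%, so that the share of false calls in the simulation was above 5% in both fits and higher with the block. The simulation with the block took the pairing as true, so its values hold only if the numbers do pair the samples. The values of both simulations belong to 200 changed genes. The p at which a gene passes depends on how many genes change. These shares therefore need not hold for the real fits, which called 14 genes without the block and 697 with it.

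Gene lists for 38 gene groups (pathways, tissues, developmental stages, gene families and material other than embryos) were written before the data were examined, and those with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01. The same test with the correlation estimated from the data, and fry, were run beside it. P-values of lists were adjusted over the 38 lists. Members past the gene test were counted over all genes tested and also adjusted over the list alone. Some lists share members: muscle and pharynx share myosin and troponin genes, the antimicrobial list shares 2 lectin genes with the C-type lectins and 7 nlp genes with the neuropeptides, and col-19 is in the yolk list and the collagen list. Chromosomes and biotypes were tested in the same way. Fisher's exact test compared the share of called genes in each list, chromosome and biotype with that of the other tested genes.

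The genes named were chosen by a rule written before the data were examined: dot-1.1, its paralogues, ced-3 and zfp-1; among called genes with a mean of at least 1 CPM and no overlap between the genotypes, the 8 highest and 8 lowest fold changes and the 4 higher and 4 lower genes with the smallest p not yet taken; and for each list up to 3 called members, or the member with the smallest p where none was called. The rule was applied to the fit without the block and, as a choice made after the data were seen, to the fit with it. Genes named outside the rule are said to be so. Alternatives to the scaling, filter, test, replicates and set test were listed before the data were examined, with DESeq2 1.42.0 and limma-voom among the tests, and others were added afterwards. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All deposited columns were used. Sequence differences, isoforms and small RNAs were not analysed here.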

Results

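Gene expression was measured by sequencing ribosomal RNA-depleted total RNA from C. elegans embryos of 2 genotypes, with 3 biological replicates each. DOT-1.1 is the worm counterpart of DOT1L, the methyltransferase of histone H3 lysine 79. CED-3 is the caspase that carries out programmed cell death in C. elegans. The comparison of dot-1.1; ced-3 double mutants with ced-3 single mutants asks which transcripts differ when dot-1.1 is mutant in ced-3 mutant animals, and the study's title ties such differences to gene activation that depends on small RNAs. Library totals were 68832040, 77957224 and 73046841 counts in the single mutants and 66316445, 72861997 and 75279479 counts in the double mutants. The first principal component of the expression values held 32.8% of the variance and had the 3 single mutants on one side, at -50.63 to -21.66, and the 3 double mutants on the other, at 12.94 to 57.32.

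The transcript of dot-1.1 (Y39G10AR.18, chromosome I, 2382953 to 2401492) was present in every library. Its counts were 4516, 2716 and 3349 in the single mutants and 3980, 2144 and 2813 in the libraries labelled double mutant. Its level was 49.3 ± 16.3 CPM (SD, n = 3) in the single mutants and 42.5 ± 17.9 CPM (SD, n = 3) in the libraries labelled double mutant, a difference smaller than the spread between replicates (log2 fold change -0.21 ± 0.33 SE, adjusted p = 0.806, edgeR). Within the pairs it was lower in the double mutant in 3 of 3, and the blocked fit gave -0.24 ± 0.093 with an adjusted p of 0.163. What the knu339 allele does to the gene is not given in the sources used here, so the level of this transcript neither supports nor contradicts the labels. The directions below rest on the genotype labels alone.

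Transcripts of ced-3 (C48D1.2, chromosome IV, 13198261 to 13204137), which is mutant in both genotypes, were at 18.7 ± 1.62 CPM (SD, n = 3) in the single mutants and 19.2 ± 2.23 CPM (SD, n = 3) in the double mutants. The DOT-1.1 partner gene zfp-1 (F54F2.2, chromosome III, 8791535 to 8806305) was at 239.5 ± 44.2 CPM against 329.1 ± 22.7 CPM (SD, n = 3 each), with an adjusted p of 0.317 in edgeR without the block. It was higher in all 3 pairs and passed the test with the block (log2 fold change 0.47 ± 0.096 SE, adjusted p = 0.0412). Exons of zfp-1 overlap those of ztf-1 on the other strand and of an unnamed gene on the same strand. Among the paralogues of dot-1.1, dot-1.4 had a log2 fold change of -0.36 ± 0.27 SE and dot-1.5 one of 0.10 ± 0.37 SE, and neither passed over all genes in either fit (adjusted p = 0.141 and 0.805 with the block). No count was found for dot-1.2, and dot-1.3 had 2 counts in 1 single mutant library. The list of DOT-1.1 and its partners, with 4 members measured, had 0 members past the test adjusted over the list alone without the block, and with it 1 higher, zfp-1, and 2 lower, dot-1.4 and dot-1.1. It was not called as a group (adjusted p = 0.823, camera), and its median, -0.055, and the direction of its test differed in sign.

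Without the block, 14 genes were higher in the double mutants and 0 were lower, and all 14 changed more than 2-fold. Of these, 12 code for proteins. The most significant was chtb-3 (T10E10.4, chromosome X, 6314529 to 6319646), which rose 4.08-fold, from 12.28 ± 1.25 to 50.1 ± 3.69 CPM (SD, n = 3 each; adjusted p = 0.00392, edgeR). The largest fold changes among the genes of the naming rule belonged to the non-coding RNA gene B0457.12 (chromosome II, 8893384 to 8893944; 8.69-fold, from 0.46 ± 0.26 to 3.99 ± 0.35 CPM), F20B10.3 (chromosome IV, 12168244 to 12169216; 6.07-fold, from 3.00 ± 0.82 to 18.2 ± 4.54 CPM), idpp-12 (W08E12.3, chromosome IV, 3303990 to 3304569; 5.75-fold) and C30B5.6 (chromosome II, 6219516 to 6222658; 5.51-fold). The adjusted p of these 4 genes lay between 0.0339 and 0.0476. The assembled locus XLOC_007476, named after its values were seen, had no annotated position. It had 0 counts in every single mutant library and 1.48, 1.07 and 1.34 CPM in the double mutants, at least 31.6-fold higher against a floor of 3 counts per library.

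Of the 14 genes, 4 lay within 129 kb on the right part of chromosome V: fbxa-136 (C18D4.2, from 17521035), C18D4.6 (from 17535586), C38D9.2 (from 17567150) and fbxa-192 (F57G4.8, from 17640672 to 17650527). The rise was 4.11-fold for fbxa-136, 3.49-fold for C38D9.2 and 2.39-fold for fbxa-192, and C18D4.6 went from 17.2 ± 1.78 to 39.6 ± 0.79 CPM (SD, n = 3 each). Of these, fbxa-136 and fbxa-192 code for F-box proteins, a family of substrate adaptors of ubiquitin ligases. The remaining genes were pals-26 (B0284.1, chromosome III, from 4375154; 4.16-fold), a member of a family linked to the response to intracellular pathogens whose exons overlap those of B0284.5 on the same strand, idpc-4 (T06E4.14, chromosome V, from 9625422; 3.77-fold), E01G6.1 (chromosome X, from 12260881; 2.58-fold) and the predicted phospholipase gene ipla-7 (T04B2.5, chromosome IV, from 10056591; 2.44-fold), the last named after its values were seen. All 14 genes were higher in every double mutant library than in every single mutant library, and all 14 were also called with the block. Such a complete separation was found for 18.5% of all tested genes, where chance gives 10% for 3 against 3.

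**Figure D1:**
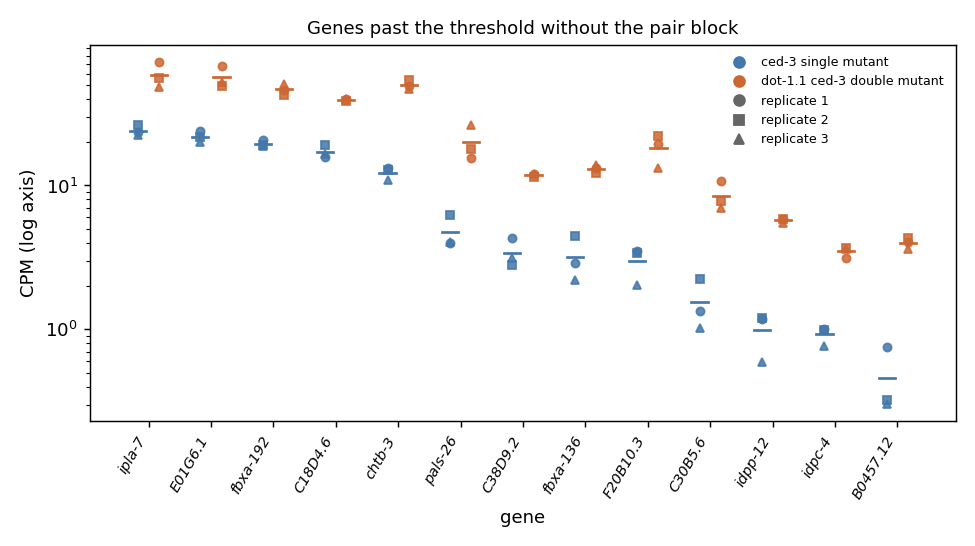
Normalised CPM (log axis) of 13 of the 14 genes higher in the double mutants without the pair block, with 1 point per library, the replicate number as the symbol and the mean of 3 libraries as a bar; XLOC_007476 is left out because its single mutant libraries are at 0. For chtb-3 the means are 12.28 and 50.1 CPM, and for each gene the 3 double mutant points lie above the 3 single mutant points.

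The count of 14 depended on single libraries. It was 2, 11 and 1 genes without single mutant replicate 1, 2 and 3, and 3, 8 and 43 genes without double mutant replicate 1, 2 and 3, and chtb-3 was called in each of these fits. At an unadjusted p under 0.05, 1315 genes were higher and 782 lower, and DESeq2 called 377 higher and 89 lower.

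With the block, 446 genes rose and 251 fell, of which 226 rose and 17 fell more than 2-fold. Among the genes of the naming rule, which asks for a mean of at least 1 CPM, the largest rises, all seen in 3 of 3 pairs, were those of F48A9.1 (14.5-fold, no annotated position), Y47H10A.5 (chromosome I, 12095482 to 12097987; 11.9-fold, adjusted p = 0.000648, edgeR), B0024.4 (chromosome V, 10297399 to 10298985; 11.9-fold) and D1005.5 (chromosome X, 1470680 to 1472980; 10.4-fold). The toxin response gene hpo-26 rose 6.89-fold, kreg-1 6.47-fold and zmp-4 6.34-fold. The galectin gene lec-6 (chromosome III, 599510 to 600366) rose 3.88-fold, from 8.996 ± 3.02 to 35.7 ± 14.7 CPM (SD, n = 3 each). The largest falls among the genes of this rule were those of B0410.3 (log2 fold change -2.93 ± 0.50 SE), whose exons overlap vang-1 on the other strand, C50E3.11 (-1.87 ± 0.36), C06A5.12 (-1.86 ± 0.31), F42A9.6 (-1.71 ± 0.19), the pseudogene F09F3.8 (-1.67 ± 0.37), T08B2.11 (-1.66 ± 0.27), Y60A9.3 (-1.43 ± 0.30) and T28C6.10 (-1.29 ± 0.18), whose exons overlap grsp-2 on the same strand. Genes under 1 CPM include some with larger fitted changes. The gene F07H5.13 fell by 0.69 on the log2 scale. The blocked count also rested on single pairs: it was 11 without pair 1, 2476 without pair 2 and 181 without pair 3. DESeq2 with the block called 932 higher and 947 lower.

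**Figure D2:**
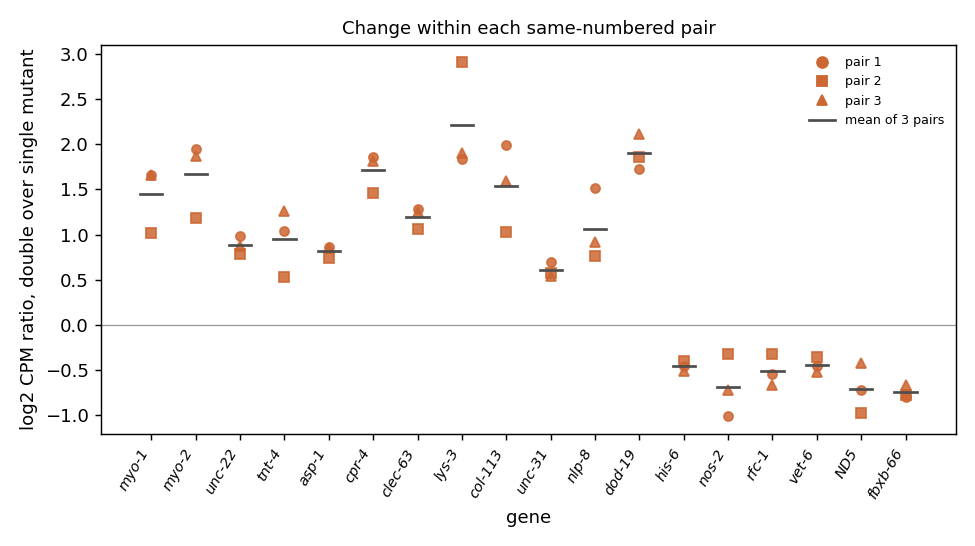
The log2 ratio of CPM in the double over the single mutant within each same-numbered pair (y axis) for 18 genes named in the text (x axis), with 1 point per pair and the mean of 3 pairs as a bar. All 3 points lie above 0 for the genes from myo-1 to dod-19, for example 1.66, 1.02 and 1.66 for myo-1, and below 0 for those from his-6 to fbxb-66. The genes were picked from those called with the block, so the choice itself favours agreement between the pairs.

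Camera with the preset correlation called 20 of the 38 gene lists, 10 higher and 10 lower in the double mutants, and called 10 and 10 with the block as well. None was called with an estimated correlation, where the lowest adjusted p was 0.214 without and 0.393 with the block. With the block, 446 of all 17365 tested genes rose and 251 fell. Fisher's exact test then called more higher members in the antimicrobial, muscle, intestine, lectin, pharynx, neuron and neuropeptide lists (adjusted p = 1.73e-07 to 0.0498). It called more lower members in the F-box list (9.55e-07) and the mitochondrial list (0.0113). It called neither in the other called lists. The test takes genes as independent, which members of a list need not be. The other 9 ways of dividing the 6 libraries into 3 and 3 gave 4 to 25 called lists, so the number of called lists does not set the genotypes apart from other divisions of the same libraries.

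The lists of muscle genes and of genes of the pharynx, the feeding organ, were called higher in the double mutants by camera. Of 46 measured muscle genes, 0 passed the gene test without the block (2 adjusted over the list alone), while with the block 8 rose and 0 fell (18 adjusted over the list alone). Of 21 pharynx genes, 0 passed without the block (3 adjusted over the list alone), and 5 rose and 0 fell with it (13 adjusted over the list alone). The pharyngeal myosin heavy chains myo-1 (chromosome I, 7258946 to 7267057) and myo-2 (chromosome X, 12468061 to 12475348) rose 2.73-fold and 3.18-fold with the block (adjusted p = 0.00575 and 0.00604, edgeR), myo-1 from 105.1 ± 31.1 to 292.6 ± 121.2 CPM (SD, n = 3 each). The giant muscle kinase gene unc-22, whose exons overlap ZK617.7 and an unnamed gene on the same strand, rose 1.84-fold, the pharyngeal gland gene phat-8 rose 7.12-fold, and the troponin T gene tnt-4 was 1.93-fold higher with an adjusted p of 0.0218. The median log2 fold change was 0.27 for the muscle list (camera adjusted p = 2.14e-07; adjusted p = 0.624 with an estimated correlation) and 0.53 for the pharynx list (1.3e-07; adjusted p = 0.39 with an estimated correlation).

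The lists of neuronal genes, neuropeptides and collagens were called in the same direction. Of 60 neuronal genes, 0 passed without the block, and 8 rose and 0 fell with it (17 adjusted over the list alone). Among them were unc-31 (1.52-fold), needed for release of dense-core vesicles, the proprotein convertase gene egl-3 (1.90-fold) and unc-33 (1.48-fold), which acts in axon growth. Of 114 neuropeptide genes, 8 rose and 0 fell with the block (14 higher and 1 lower adjusted over the list alone) and 0 passed without it (6 adjusted over the list alone). Of these 8 genes, nlp-27, nlp-29 and nlp-34 are also among the antimicrobial effector genes below. The insulin-like gene ins-20 rose 12.1-fold from a level of 0.093 ± 0.10 CPM, nlp-34 rose 2.70-fold and nlp-8 2.09-fold. Of 117 collagen genes, the structural genes of the cuticle, 5 rose and 0 fell with the block (5 adjusted over the list alone) and 0 passed without it (2 adjusted over the list alone). They included col-113 (2.90-fold, from 26.98 ± 5.72 to 78.8 ± 20.1 CPM, SD, n = 3 each), col-103 (3.04-fold) and col-109 (2.04-fold). Exons of col-113 and col-103 overlap genes on the other strand. The share of higher collagen genes with the block, 4.27%, was not called different from that of other genes (adjusted p = 0.672, Fisher's exact test). The medians were 0.15, 0.43 and 0.45 for neurons, neuropeptides and collagens, with camera adjusted p of 4.05e-05, 6.08e-08 and 1.02e-08. With an estimated correlation the adjusted p was 0.598, 0.547 and 0.547.

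Lists of defence genes and of intestinal genes were called higher by camera as well, although most of their members did not pass the gene test, and 18 of the 31 intestinal genes lay above 0 without the block. Of 51 antimicrobial effector genes, 0 passed without the block (13 higher adjusted over the list alone), while 12 rose and 1 fell with it (25 higher and 2 lower adjusted over the list alone). The lysozyme gene lys-3 rose 4.66-fold (adjusted p = 0.00676, edgeR), the infection response gene irg-2 8.28-fold from 0.26 ± 0.24 CPM, and the lectin gene clec-67 2.41-fold. Of 115 C-type lectin genes, 12 rose and 2 fell with the block (18 higher and 3 lower adjusted over the list alone), and 0 passed without it (9 adjusted over the list alone). Examples were clec-63 (2.29-fold), clec-41 (2.88-fold) and F56A4.2 (2.07-fold). Of 36 genes of the intracellular pathogen response, pals-26 passed in both fits and 35 did not (2 adjusted over the list alone without the block, 6 with it). Of 31 intestinal genes, 7 rose and 0 fell with the block (8 adjusted over the list alone), and 0 passed without it (7 adjusted over the list alone), among them the proteases cpr-4 (3.27-fold, from 4.25 ± 2.28 to 13.3 ± 5.00 CPM), cpr-3 (4.55-fold) and asp-1 (1.76-fold). The median log2 fold changes were 0.60, 0.23, 0.45 and 0.073 in the order given, with camera adjusted p of 3.08e-08, 2.66e-05, 2.66e-05 and 0.00747. With an estimated correlation the adjusted p was 0.39, 0.214, 0.214 and 0.278.

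Yolk protein genes and the adult collagen gene col-19, which mark adult tissue, had a median log2 fold change of 1.84 over 6 measured members at very low levels. None passed over all genes in either fit, and 4 were higher adjusted over the list alone in both. The summed level was 1.85 ± 0.48 CPM in the single mutants and 3.63 ± 0.45 CPM in the double mutants (SD, n = 3 each). The list was called by camera (adjusted p = 1.37e-06; adjusted p = 0.214 with an estimated correlation) and was the only list called by fry without the block (adjusted p = 0.0256), a call that ended with the block (adjusted p = 0.115). In this list, col-19 had 0 counts in the single mutants and 10, 14 and 12 in the double mutants, at least 4.08-fold higher.

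The lists of genes of early embryos, the germ line and the cell cycle were called lower in the double mutants by camera, with few single genes past the test and 0 of them without the block. With the block, 4 of 80 histone genes fell (24 adjusted over the list alone), among them the histone genes his-6 (log2 fold change -0.46 ± 0.086 SE, adjusted p = 0.0351, edgeR), F54E12.4 (-0.40) and the linker histone gene hil-5 (-0.45). Histone genes are near-identical copies, so reads can be shared between them. Of 31 early zygotic genes, vet-6 fell (-0.45 ± 0.081) and 30 did not pass (7 lower adjusted over the list alone). Of 33 meiosis genes, zim-2 (-0.58), which overlaps zim-1 on the same strand, and htp-2 (-0.63) fell (6 adjusted over the list alone), and of 56 genes of DNA replication and the cell cycle, rfc-1 fell (-0.52 ± 0.096; 1 adjusted over the list alone). Of 31 genes of germ granules and germ cell fate, nos-2 (-0.69) and iff-1 (-0.47) fell and the RNA helicase gene vbh-1, which overlaps K09H9.11 on the same strand, rose (0.37), with 4 lower and 1 higher adjusted over the list alone. Of 38 oocyte and maternal transcripts, 0 passed (3 lower adjusted over the list alone), and pos-1 was at -0.46 with an adjusted p of 0.0566. None of 39 lineage transcription factors passed in either way of adjusting, and the lowest p belonged to fkh-3 (-0.50, adjusted p = 0.0664). By Fisher's exact test with the block, the share of lower genes was called larger in none of these lists (lowest adjusted p = 0.272, for histones). The medians were -0.20 for histones, -0.44 for early zygotic genes, -0.26 for meiosis, -0.16 for replication, -0.18 for germ granules, -0.15 for oocyte transcripts and -0.20 for lineage factors. Camera gave adjusted p of 7.49e-07, 1.46e-05, 0.000232, 0.00033, 0.0093, 0.0465 and 0.00127 in that order, and 0.624, 0.696, 0.746, 0.787, 0.743, 0.787 and 0.696 as adjusted p with an estimated correlation.

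Within pairs, the mean log2 level of 87 early zygotic and replication genes was lower in the double mutant in 3 of 3 (differences of -0.396, -0.163 and -0.316), and that of the 353 muscle, pharynx, neuron, neuropeptide and collagen genes was higher in 3 of 3 (0.623, 0.163 and 0.475). An exact two-sided sign-flip test of 3 pairs gave p = 0.25 for both, the smallest it allows. Both sets were made of lists already called by camera in these same libraries, so their directions are no separate support.

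Some of these calls rested on single libraries. Oocyte and maternal transcripts were not called without single mutant replicate 1 or 2 or without double mutant replicate 1 or 3 (adjusted p = 0.0884, 0.114, 0.831 and 0.295), and their median was 0.017 without double mutant replicate 1. Without double mutant replicate 3, germ granule genes and replication genes were not called (adjusted p = 0.226 for both), and without double mutant replicate 1 lineage factors were not (adjusted p = 0.0511).

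The lists of small RNA pathway genes and of the large F-box and BATH family were also called lower by camera. Of 60 small RNA pathway genes, 0 passed without the block, and 4 fell and 0 rose with it (10 lower and 2 higher adjusted over the list alone). The RNA interference gene rde-2 (-0.56 ± 0.11 SE), which overlaps hint-1 on the same strand, the RNA phosphatase gene pir-1 (-0.50 ± 0.095), which overlaps sym-2 and twk-4 on the other strand, and the RNA transport gene sid-5 (-0.70 ± 0.14) had the smallest p, with adjusted p of 0.0397, 0.0359 and 0.0388. Of 309 F-box and BATH genes, fbxa-192 and fbxa-136 rose without the block (3 adjusted over the list alone). With it, 7 rose and 20 fell (8 higher and 43 lower adjusted over the list alone), fbxb-66 among those that fell (-0.75 ± 0.085). The medians were -0.14 and -0.23 (camera adjusted p = 0.00747 and 0.00196; adjusted p = 0.696 and 0.787 with an estimated correlation). The small RNA list was not called without double mutant replicate 1 (adjusted p = 0.0774), nor the F-box list without single mutant replicate 2 or double mutant replicate 3 (adjusted p = 0.121 and 0.234).

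Several RNAs of the mitochondrial genome fell in the double mutants with the block. The large and small mitochondrial ribosomal RNAs (MTCE.33, 10403 to 11354, and MTCE.7, 898 to 1593 on the mitochondrial chromosome) fell by 0.99 and 0.82 on the log2 scale with the block (adjusted p = 0.0037 and 0.0044, edgeR), and together took 9.50, 11.02 and 6.92% of the counts in the single mutants and 4.96, 6.16 and 4.04% in the double mutants. Without the block their adjusted p was 0.213 and 0.224. The libraries were depleted of ribosomal RNA, so the levels of these RNAs may also depend on the depletion in each library, which was not tested. The nuclear ribosomal RNA left after depletion moved the other way, with 0.747, 0.769 and 1.09% of the counts in the single mutants and 2.71, 1.34 and 1.19% in the double mutants, with no overlap between the genotypes. Of 12 mitochondrial protein-coding genes, 3 fell with the block (7 adjusted over the list alone) and 0 without it (1 adjusted over the list alone): ND5 (-0.71 ± 0.12 SE), ND4 (-0.51 ± 0.087) and ND6 (-0.97 ± 0.17). Exons of ND5 and ND6 touch those of ND3 and ND4L, and those of COX1 and COX2 touch MTCE.27 and MTCE.32. The median was -0.50 (camera adjusted p = 0.000527; adjusted p = 0.624 with an estimated correlation). Within this list, COX1 had 5720 counts in single mutant replicate 1 and 4311 in double mutant replicate 3, against 158676 to 300823 in the other 4 libraries, and COX2 had 1 count in double mutant replicate 3 against 45361 to 85571 elsewhere.

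**Figure D3:**
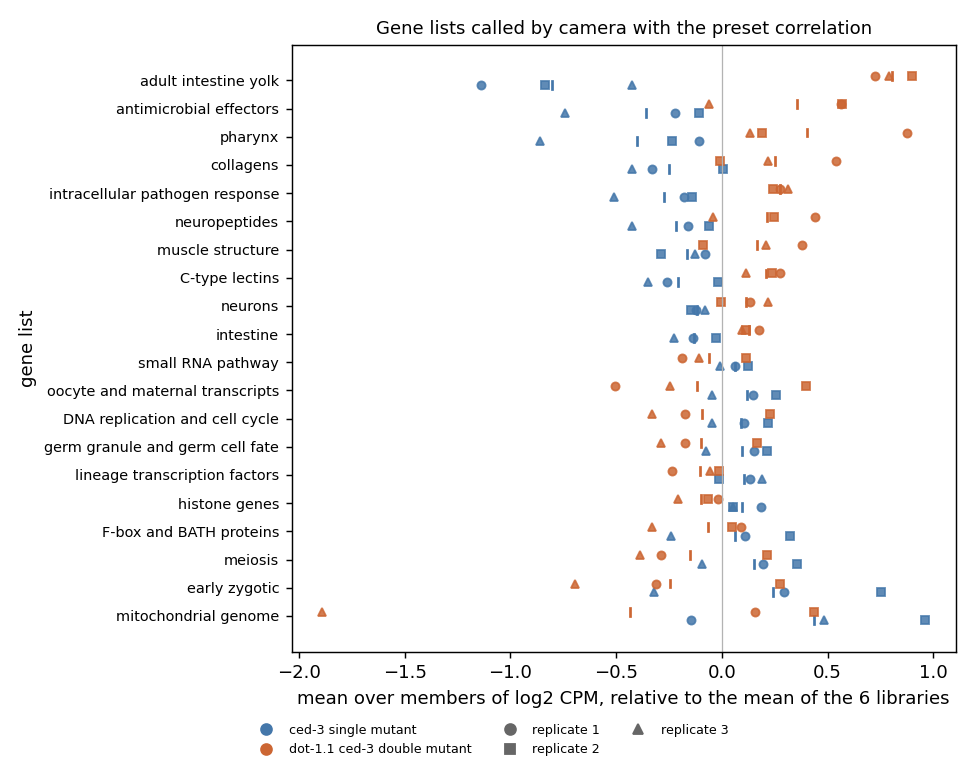
Mean over the members of each of the 20 called lists (y axis) of log2 CPM in each library, relative to the mean of the 6 libraries (x axis), with 1 point per library, the replicate number as the symbol and the mean of 3 libraries as a bar. The genotypes separate for the yolk list (-1.14 to -0.43 against 0.72 to 0.90) and overlap for early zygotic genes (-0.32 to 0.75 against -0.69 to 0.27).

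The other 18 lists were not called by camera. Heat shock genes had a median of 0.33 (adjusted p = 0.193), and with the block a median of 0.21 and a mean of 0.045, with 10 of 25 members below 0. Of these genes hsp-110 (1.42-fold) and hsp-17 (1.86-fold) rose with the block, and 5 were higher and 1 lower adjusted over the list alone. The median was 0.080 for the unfolded protein response of the endoplasmic reticulum (adjusted p = 0.548), -0.033 for that of mitochondria (0.591; ubl-5 fell by 0.74 with the block), 0.058 for oxidative and xenobiotic stress genes (0.488), -0.078 for cell death and engulfment genes (0.332; the p53-related gene cep-1 fell by 0.45 with the block), -0.067 for sperm genes (0.961), -0.19 for Hox genes (0.207), -0.077 for epidermis and cuticle (0.258), -0.065 for chromatin modifiers (0.0948; the methyltransferase gene lin-59 rose 1.34-fold with the block) and -0.11 for sex determination and dosage compensation (0.0608). It was 0.074 for ribosomal proteins (0.16), -0.032 for the proteasome (0.68; pbs-5 rose 1.37-fold with the block), -0.027 for the nuclear-encoded respiratory chain (0.284; cox-7C and asb-1 fell by 0.66 and 0.41 with the block), -0.0058 for chemoreceptors (0.536; srh-71 rose 1.94-fold and srt-42 5.08-fold with the block) and -0.19 for long intergenic non-coding RNAs (0.0948; linc-128 rose 2.03-fold with the block). Nuclear hormone receptors (-0.012, adjusted p = 0.166) and insulin and DAF-16 targets (-0.012, adjusted p = 0.353) had means of 0.012 and 0.20, of the other sign. With the block the oxidative and xenobiotic list had a median of -0.012 and a mean of 0.093, and the sperm list a median of -0.067 and a mean of 0.0040. Adjusted over the list alone, 1 DAF-16 target was higher without the block and no other member of these 18 lists passed. With the block, besides the heat shock list and that of DOT-1.1 and its partners, 2 DAF-16 targets and 1 proteasome gene were higher, and 2 nuclear hormone receptors, 2 genes of the respiratory chain, 1 of the mitochondrial unfolded protein response and 1 of cell death and engulfment were lower, adjusted over the list alone. Among the receptors, 2 rose and 4 fell with the block, including nhr-127 (-0.83; exons shared with nhr-218 on the same strand), nhr-43 (-0.74) and nhr-165 (-1.77), and among the DAF-16 targets dod-19 rose 3.73-fold, from 9.20 ± 2.94 to 33.6 ± 7.14 CPM (SD, n = 3 each; adjusted p = 0.00102, edgeR with the block), and dod-22 rose 3.20-fold.

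Called genes lay on several chromosomes. Of the 14 genes, 5 lay on chromosome V, 3 on IV, 2 each on II and X and 1 on III. With the block, chromosome V held 120 of the higher genes among 3507 tested, a larger share than elsewhere (adjusted p = 0.00362, Fisher's exact test, two-sided; 0.618 without the block), and chromosome X held 18 of the lower genes among 2650 tested, a smaller share (adjusted p = 0.000453; 1 without the block). On the mitochondrial chromosome 5 of 17 genes were lower with the block (adjusted p = 2.28e-05; 1 without the block). These 5 include the 2 ribosomal RNAs, whose levels may depend on the depletion. Fisher's test takes genes as independent. The estimated correlation between the mitochondrial genes was 0.484 without the block and 0.16 with it. Neighbouring higher genes on chromosome V may not be independent either, so these p-values may be too low. The mitochondrial chromosome was the only one called by camera (median -0.62 over 17 genes, adjusted p = 8.51e-06; adjusted p = 0.819 with an estimated correlation). By biotype, the 939 genes annotated as non-coding RNA had a median of 0.27 (camera adjusted p = 0.000116; adjusted p = 0.322 with an estimated correlation), the 181 small nucleolar RNA genes one of 0.21 (0.0305, and 0.0809 with the block; adjusted p = 0.496 with an estimated correlation) and the 15081 protein-coding genes one of -0.034 (0.0101; adjusted p = 0.185 with an estimated correlation), while their mean was 0.032, of the other sign than the camera call. Among non-coding RNA genes 13 rose (1.38%, against 2.69% of protein-coding genes) and 0 fell with the block. Their share of higher genes was not called different from that of other genes (adjusted p = 0.0799, Fisher's exact test, two-sided), and their share of lower genes was smaller (adjusted p = 8.38e-06). Genes were not matched on expression level, so these shares were not separated from the power to call a gene.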

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

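Among the alternatives, DESeq2 with the replicate block, the blocked fits with a pair left out or another scaling, and both fits with a covariate were chosen after the data were seen. The 14 genes (14 higher, 0 lower, 14 over 2-fold) became 26, 26 and 0 with library totals only and 26 over 2-fold, 22 with protein-coding genes only (22 higher, 22 over 2-fold), 8 with non-robust empirical Bayes (8 higher, 8 over 2-fold) and 4 with no filter on low counts (4 higher, 4 over 2-fold), where more genes are tested. They were 15 with median-of-ratios size factors, 21 with totals without the 50 most abundant genes, 18 with a filter of 1 CPM and 14 with limma-voom, which shared 11 genes with edgeR. DESeq2 called 466 genes (377 higher, 89 lower, 274 over 2-fold, 80.9% higher), all 14 among them. The cause of these differences was not tested. With single libraries left out, the number changed ran from 1 to 43, the number over 2-fold from 1 to 43, higher from 1 to 42 and lower from 0 to 1. Fewer libraries leave less power, and 43 were called without double mutant replicate 3.

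With the replicate block, which takes the pairing into the model, 697 genes changed (446 higher, 251 lower, 243 over 2-fold), 64% of them higher. With the replicate block in DESeq2, 1879 changed (932 higher, 947 lower, 360 over 2-fold), 49.6% of them higher. The replicate block with pair 1 left out called 11 (9 higher, 2 lower, 11 over 2-fold), with pair 2 left out 2476 (1361 higher, 1115 lower, 656 over 2-fold) and with pair 3 left out 181 (160 higher, 21 lower, 142 over 2-fold). With median-of-ratios size factors the replicate block gave 666 (429 higher, 237 lower, 234 over 2-fold), and with library totals only 933 (648 higher, 285 lower, 320 over 2-fold, 69.5% higher). A covariate for the early-embryo score gave 39 genes without the block (39 higher, 0 lower, 39 over 2-fold), 13 of them among the 14. With the replicate block and this covariate 27 were called (4 higher, 23 lower, 27 over 2-fold), 0 of them among the 697 of the replicate block alone. This last fit leaves 1 residual degree of freedom, and so does each blocked fit with a pair left out. The replicate block alone also leaves few, so its 697 calls rest on little replication too. No scaling moved the median log2 fold change of all genes by 0.1. Besides the gene calls and Fisher's tests given with the results, the replicate block changed no camera call of a gene list or chromosome, and of the biotypes it ended that of small nucleolar RNAs.

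Of the 20 gene lists called, 0 were called with an estimated correlation, with or without the replicate block, and 1 with fry without the block and 0 with it. Likewise 0 of 1 chromosomes and 0 of 3 biotypes were called with an estimated correlation in either fit. Across the other alternatives 19 to 25 lists were called. For dot-1.1, dot-1.5 and ced-3, which passed over all genes in neither fit, the log2 fold change of dot-1.1 ran from -0.62 to 0.088 with single libraries left out (0.088 without single mutant replicate 1 and 0.035 without double mutant replicate 2), that of dot-1.5 from -0.083 to 0.49 (-0.011 without single mutant replicate 1, -0.00069 without double mutant replicate 2), and that of ced-3 from -0.025 to 0.10 (-0.021 without double mutant replicate 2). In the simulation at these totals, with 200 genes changed, 41.4% of the genes changed 2-fold were called without the block. That share need not hold where fewer genes pass, and depth was not varied. The yolk genes other than vit-1 rest on 0 to 59 counts per library.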

Other observations

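The tests of adult tissue, of embryo age within pairs, of the single genes of the segment, of a mislabelled library and of the dot-1.1 neighbourhood were chosen only after the values they rest on were seen. The genes of the next paragraphs were chosen after their values were seen.

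Some genes had no count in any library of one genotype. At 0 counts in every single mutant library and at 5 or more counts in every double mutant library were 10 genes, among them Y59E9AR.2 (17, 23 and 15 counts in the double mutants, at least 6.26-fold higher against a floor of 3 counts per library), Y38H6C.13 (15, 15 and 13 counts, at least 4.91-fold), the F-box gene fbxc-55 (8, 25 and 6 counts, at least 4.41-fold) and the chemoreceptor gene srx-43 (14, 6 and 6 counts, at least 3.03-fold). In the other direction there were 4 genes, W09D6.4 (11, 20 and 9 counts in the single mutants, at least 4.27-fold lower in the double mutants), K01D12.15, cyp-35B1 and grl-19. Another division of the 6 libraries into 3 and 3 gave 15 such genes against these 14, so their number does not set the genotypes apart.

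Heat shock genes followed the replicate number more than the genotype. The mean log2 level of the list was 0.46, 0.14 and -0.67 relative to the mean of all libraries in single mutant replicates 1, 2 and 3, and 1.04, -0.25 and -0.73 in the double mutants. The chaperone gene F44E5.4 was at 3118, 1441 and 906.1 CPM in the single mutants and 6355, 1209 and 835.2 CPM in the double mutants, and its near-identical copy F44E5.5 had 3165, 1459 and 915.1 CPM and 6471, 1216 and 842.4 CPM, so reads can be shared between the copies.

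Of the mitochondrial genes other than COX1 and COX2, the 9 with enough counts had a median ratio of 0.681 between the 2 libraries with little COX1 and the other 4, with a range from 0.27 to 0.925. The COX1 level missing from these libraries was 3130 CPM on average, and the largest gain of another gene in both over its highest level elsewhere was 79.9 CPM, for icd-1. No explanation was tested.

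The first pattern weighed is that several lists of differentiated tissues were called higher and lists of early embryos lower in the double mutants, as a collection of older embryos could give. Not every tissue followed it. The epidermis and cuticle list was not called and had 14 members above 0 and 30 below without the block (median -0.077). Adult tissue is argued against, since the yolk list gained 1.78 CPM and the muscle list 4380 CPM, a ratio of 0.000405. Embryo age stays open, because the fits differ: with a score of 87 early zygotic and replication genes as a covariate and no block, the 353 members of the muscle, pharynx, neuron, neuropeptide and collagen lists had 0.944 of their median log2 fold change (0.825 to 1.09 over resampled genes, 0.632 to 1.42 with single libraries left out), but with the block and the score the median went from 0.361 to -0.105. The fit without the block was the one planned, yet its score also carries differences between the pairs. Within pairs the score was lower in the double mutant in 3 of 3 (-0.291 ± 0.118, SD, n = 3 pairs). The fit with both the block and the score leaves 1 residual degree of freedom. It calls 4 higher and 23 lower genes, 0 of them among the 697 of the block alone. For the 14 genes the median kept 1.03 of its value without the block (0.981 to 1.12) and 0.824 with it (0.469 to 1.18), so age may account for part of it, and neither these data nor the design separate age from an effect of the dot-1.1 genotype.

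The second pattern is that genes of propionate breakdown, and pmp-5 with them, were low in double mutant replicate 2 alone. The acyl-CoA dehydrogenase gene acdh-1 was at 1.2 CPM there against 476 to 1080 CPM in the other 5 libraries, hphd-1 at 23.1 against 323 to 526 CPM and pmp-5 at 3.8 against 84.7 to 166 CPM. A candidate explanation is more vitamin B12 in that culture, which is known to repress acdh-1 and this pathway. It predicted a fall of 3 genes of the pathway not yet looked at. All 3 were lower there by at least 1.5-fold than in every other library, ech-6 by 4.12-fold, hach-1 by 2.22-fold and alh-8 by 1.79-fold. Any cause that lowers the whole pathway would give the same fall, so these genes cannot single out vitamin B12. A mislabelled single mutant library is argued against, since over 100 genes picked without that library it lay at 0.729 of the way from the single to the other double mutants (0.665 to 0.861), and the single mutants expressed these genes at the higher level. Bacteria or medium were not described per library, so the cause stays open.

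The third pattern concerns where the higher genes lie. Linkage to the dot-1.1 locus on chromosome I is argued against as the main cause of the calls: 0 of the 14 genes were placed on that chromosome. With the block, 22 of 580 tested genes within 2 Mb of the locus were called higher or lower (3.79%, against 662 genes or 4.01% elsewhere), an odds ratio of 0.943 (0.582 to 1.46, Fisher's exact test, p = 0.914). The higher genes near the locus were not tested alone. A rise of the whole 129 kb segment of chromosome V that holds 4 of the 14 genes is argued against. The 10 other genes tested there had a median log2 fold change of -0.087 (-0.325 to 0.326). Of these, 7 were under 1 CPM and show little. They ran from -0.856 for fbxa-172 to 1.27 for F57G4.4, which lies next to fbxa-192 and was called in neither fit. The 95% intervals of the 3 others ended at 1.12 or lower without the block and 0.974 or lower with it. These ends lie under the smallest rise of the 4 genes, 1.2 for C18D4.6, which has an error of its own (± 0.138 SE). A smaller change or one of part of the segment stays open. Genes higher with the block were neighbours in 38 pairs, against a mean of 11.4 and at most 24 in 10000 permutations of gene positions within chromosomes (permutation p = 0.0001, the smallest they can give), and examples are W08E12.5 to W08E12.2 on chromosome IV and B0457.12 to B0457.10 on chromosome II. Of the 38 pairs, 6 share exons and 6 share the first part of their symbol (in unc-73 and unc-89 a phenotype, not a family), so local clusters of higher genes may exist, but paralogues under unlike names and co-expressed tissue genes that lie together could give the same count and were not separated from it.

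Divisions of the samples were compared last. Of the 10 divisions of the 6 libraries into 3 and 3, 1 gave as many genes as the real one without the block, the real one itself with 14, and the highest other gave 1. Of the 4 divisions that part all 3 pairs, 1 gave as many with the block, the real one with 697, and the highest other gave 0. For gene lists 2 of 10 divisions gave as many as the 20 called, with 25 as the highest other, for chromosomes 6 of 10 gave as many as 1, with 2 as the highest other, and for biotypes 4 of 10 gave as many as 3, with 6 as the highest other. These divisions are too few for a share under 0.05.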
